A study of Dunaliella salina with 9 samples.

How the data were processed

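The study sequenced total RNA of 9 samples of cultured Dunaliella salina, 3 for each of white, red and blue light. Per the labels' protocols, cells in mid-exponential phase were moved to fresh medium under the light to be tested, RNA was taken with Trizol from frozen pellets, and libraries were made from 1.5 µg RNA with the NEBNext Ultra RNA kit for Illumina. How long the cells stayed under each light, and whether each sample came from a culture of its own, is not given in the sources used here; if not, p-values measure only the spread between these samples. Nor is it given whether the samples of all 3 lights share strain, date and batch, so a batch could not be separated from the light. The aligner, the counting tool, the assembly and the annotation are not given there either. The submitters' processing notes name DESeq 1.10.1.

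Each library has 1 deposited table with an identifier of the form Cluster-n.m, a read count and an FPKM value for 115975 clusters, in the same order in all 9 tables. The deposited counts are estimated counts and not scaled: between 21.6% and 33.9% of the values per library are not whole numbers, as when reads that match several clusters are divided between them, and totals differ between libraries. The FPKM values deposited by the authors are counts per kilobase of effective length and per 1e6 counts of the library, judged from the values. They were used here only to derive each cluster's effective length, as the median over libraries in which the cluster had at least 50 counts. No cluster identifier matched any of the 16683 genes of the reference table for the D. salina assembly Dunsal1 v. 2, so gene names and positions were not used here. The gene lists set out before the data were examined (carotenoid and chlorophyll synthesis, light harvesting, photoreceptors, stress and others) could therefore not be tested. A cluster can be a gene, an isoform or an allele, and reads of near-identical sequences can be split between clusters, so that a change in a cluster can be a change in how reads were divided.

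Estimated counts were rounded to whole numbers. Of the 115975 clusters, 6336 had no counts at all and 38376 passed edgeR's filterByExpr (at its default minimum of 10 counts per library and 15 in total), and these held 99.0% to 99.4% of the counts. Counts were scaled by TMM and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit, robust, and glmQLFTest), with all 9 libraries in 1 fit and the light as the only term. The 3 contrasts were red against white, blue against white and blue against red. Adjusted p-values are Benjamini-Hochberg values over all tested clusters within a contrast, with 0.05 as the threshold. CPM values are TMM-scaled, and classes of abundance use the mean over the 9 libraries. Shares of counts and numbers of clusters detected use unscaled counts. Where a group had no counts, the fold is a bound against 3 counts over the whole group. It uses the pooled counts of the other group, so single libraries can lie below it. A count of 0 in a single library allows up to 0.116 (red 1) to 0.224 CPM (white 3), which covers counting error only, as the reads carry no molecular identifiers in the sources used here.

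The groups, the tests, the rule for named clusters and the alternatives were fixed before the data were examined, except where the text says otherwise. The share of counts in short clusters, the shares of counts in changed clusters and the 8-fold counts were added after seeing the data. As identifiers could not be paired with names, the rule names 4 clusters in the whole text: the one with the largest increase and the one with the largest decrease in red against white and in blue against white, among clusters past the threshold with a mean of at least 10 CPM and no overlap between the libraries of both groups, and the next cluster for blue where the same one was picked. The alternatives were size factors (RLE) or library totals in place of TMM, DESeq2 1.42.0, limma-voom (limma 3.58.1), no filter or a stricter one (mean of 10 CPM), a fit of only the groups compared, the replicate number as a block, each library left out in turn, and stricter thresholds. Clusters with whole counts only, quality weights per light group and the removal of the 100 most abundant clusters were added after seeing the data.

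No 2 libraries of a group were alike within sampling noise. A chi-square of the counts per cluster, near 1 for repeat runs of 1 library, was 8.14 or more for every pair within a light, with 148 for white 1 and white 2. The fitting code was tested on simulated data for red against white, with 200 of 38376 clusters changed. It recovered 37.0% of the clusters changed 8-fold and 1.0% of those changed 2-fold, or 74.4% and 3.7% of those with a mean of at least 10 CPM, with 0 false calls. Where few clusters change, 2-fold changes are thus mostly beyond the reach of this design.

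Similarity between the red and blue responses was set against 10 simulations of unchanged groups, in which white libraries were drawn with the spread of the white group and the others with that of red and blue. Numbers of clusters detected and shares of counts were compared with two-sided exact permutation tests. Figures were drawn with matplotlib 3.10.9.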

Results

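RNA was sequenced from 9 samples of cultured Dunaliella salina, a salt-tolerant unicellular green alga known for accumulating β-carotene. The cells were in mid-exponential growth. They received cool white light (3 samples), red light of 660 nm (3 samples) or blue light of 450 nm (3 samples), all at 50 µmol photons per square metre per second. The title of the series sets the question of how red and blue light change the transcriptome with regard to carotenoid synthesis. White light is the reference in what follows. Total counts were 18314153, 19888088 and 16279167 in white 1 to 3, 24526786, 17674678 and 21732972 in red 1 to 3, and 17905778, 19921151 and 18518605 in blue 1 to 3. The files count reads on 115975 numbered transcript clusters and do not pair the cluster identifiers with gene names, so that enzymes of carotenoid synthesis and other pathways are not named here. The series describes the 9 samples as biological, and 38376 clusters had enough counts to be tested.

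Fewer clusters were detected under white light than under red or blue light, and the most abundant clusters took more of the counts. On average 57460 ± 6920 clusters had at least 1 count in white (SD, n = 3), 78963 ± 3514 in red and 73400 ± 3222 in blue. After all libraries were thinned to the smallest total, the means were 56418 ± 6942 in white, 75781 ± 3052 in red and 71645 ± 2534 in blue. The 10 most abundant clusters took 11.4% ± 3.0 of the counts in white, 6.98% ± 0.12 in red and 5.09% ± 0.42 in blue. Clusters with an effective length under 300 bases took 5.998% ± 1.70 in white, 2.91% ± 0.13 in red and 2.54% ± 0.25 in blue. For each of these measures every white library lay on the same side of every red and every blue library, and two-sided exact permutation tests gave p = 0.1 for both comparisons with white, the smallest value that 3 against 3 libraries allow (0.14 after Benjamini-Hochberg adjustment over 21 such tests). Between blue and red, the numbers of clusters detected overlapped (exact permutation p = 0.2). The shares of the 10 most abundant clusters and of short clusters were lower in every blue library than in every red one (exact permutation p = 0.1 for both, 0.14 adjusted).

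The first principal component of log2 CPM, with 59.3% of the variance, separated the white libraries from all others. Red and blue libraries separated on the third component, with 7.83% of the variance. The white libraries also differed more from each other than the others did. The correlation across clusters was 0.802 between white 1 and white 2, 0.883 between white 1 and white 3 and 0.895 between white 2 and white 3, against 0.902 to 0.918 for pairs within red and within blue. The biological coefficient of variation estimated by edgeR was 80.1% in white, 44.0% in red and 47.8% in blue.

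**Figure D1:**
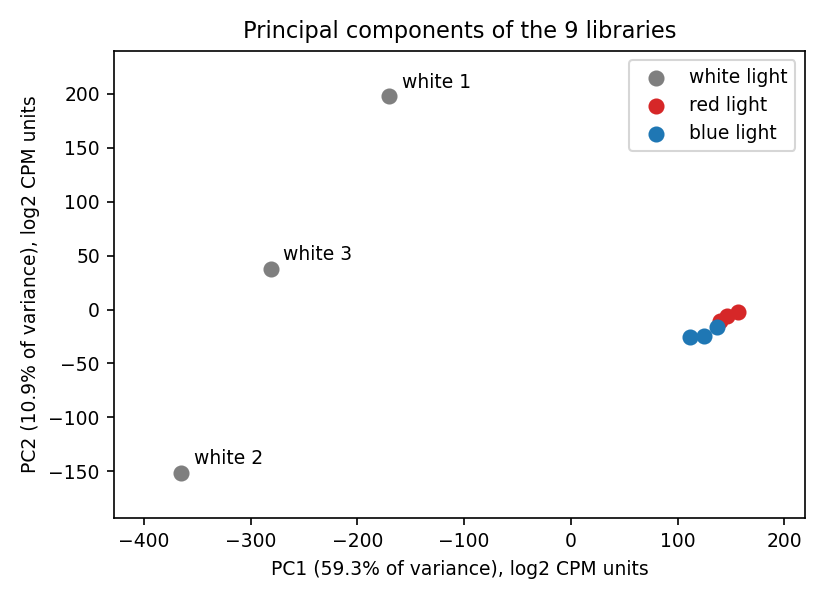
Scores of the 9 libraries on the first (horizontal axis) and second (vertical axis) principal components of log2 CPM over the 38376 tested clusters; each point is 1 library, coloured by light. The red and blue libraries lie together between 111.6 and 156.6 on the first component, while white 1, white 3 and white 2 lie apart at -170.4, -281.1 and -365.2. On the second component white 1, white 3 and white 2 lie at 198.1, 37.9 and -151.2, and red and blue between -25.4 and -2.

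Red light was compared with white light to find the clusters that respond to a narrow red band at the same photon flux. In red, 6531 clusters rose and 6481 fell, together 33.9% of those tested (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 5881 rose and 4498 fell at least 2-fold, and 3364 rose and 1648 fell at least 8-fold. The clusters that rose held 7.57% ± 1.6 of the counts in white and 22.1% ± 0.099 in red (SD, n = 3). Those that fell held 46.7% ± 5.2 in white and 20.7% ± 0.21 in red. These shares describe clusters selected for their difference.

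Abundant clusters fell more often than rare ones. Of the clusters with a mean above 100 CPM, 265 rose and 490 fell in red, and of those with 10 to 100 CPM, 1474 rose and 2917 fell. Between 1 and 10 CPM the numbers were close, with 2799 that rose and 2537 that fell. Under 1 CPM, 1993 rose and 537 fell. Which direction had more calls in each of the 4 classes depended on the analysis. With library totals as the only scaling more clusters rose than fell above 100 CPM (415 against 324) and from 10 to 100 CPM (2096 against 1938). In limma-voom with a spread of its own for each light group, more were called lower than higher under 1 CPM (534 against 83) and from 1 to 10 CPM (2236 against 1523). Limma-voom without that setting gave 2023 that rose and 647 that fell under 1 CPM, and 3759 and 2575 from 1 to 10 CPM. The median log2 fold change of all clusters was 0.433 with that setting and 0.434 without it, so higher calls were lost with little change in the median fold. The scaling moved the median of all clusters from 0.31 on the log2 scale with TMM to 0.60 with library totals.

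The cluster that rose most in red by the naming rule was Cluster-15686.41815 (effective length 1499 bases). It had no counts in the 3 white libraries, 734 ± 540 CPM in red (SD, n = 3) and 530 ± 300 CPM in blue. Against a floor of 3 counts over the white group, the pooled counts gave a bound of 11100-fold in red (edgeR adjusted p = 0.00068). The bound was 8020-fold in blue (edgeR adjusted p = 0.00074). The red mean rested in large part on red 3, with 1360 CPM beside 431 in red 1 and 411 in red 2, and without red 3 the fitted log2 difference in red was 15.97 in place of 16.80. With limma-voom the adjusted p was 0.11 in red and 0.13 in blue, within a range over the alternatives that tested it of 6.9e-30 to 0.53 in red and 4.3e-28 to 0.57 in blue. The cluster with the largest fall in red was Cluster-15686.51590 (2558 bases), which had no counts in red or blue. Its mean in white, 1440 ± 2300 CPM, rested on white 1, with 4140 CPM beside 90.5 in white 2 and 80 in white 3. Of the 72973 counts in white, 70496 were from white 1. Against a floor of 3 counts over the red group, the pooled white counts gave a bound of 35100-fold, which white 2 and white 3 alone do not reach. The edgeR adjusted p in red was 0.041. Without white 1 the fitted log2 difference was -13.72 in place of -17.77. That p was 0.00045 without white 1 and 0.063 without white 3, and between 0.083 and 0.088 without any 1 of the red libraries. With limma-voom it was 0.44.

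Whether the white samples shared strain, date and batch with the others is not given in the sources used here, so differences from white are differences between these groups of samples. The number of clusters changed in red depended on which libraries were used. It was 19979 without white 1, 8639 without white 3, 7675 without red 1 and 8131 without red 2. With library totals as the only scaling, 8066 clusters rose and 4544 fell. The spread was pooled over all 3 lights although it was larger in white, so the main count may be too high. A fit of the red and white libraries alone, which has fewer libraries to estimate the spread, called 9310 clusters.

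Blue light was compared with white light in the same fit. In blue, 5424 clusters rose and 5637 fell, or 28.8% of those tested (edgeR's quasi-likelihood test, adjusted p under 0.05). At least 2-fold changes were seen in 4778 clusters that rose and 3911 that fell, and at least 8-fold changes in 2915 and 1405. The clusters that rose held 7.39% ± 1.2 of the counts in white and 22.1% ± 0.70 in blue (SD, n = 3). The clusters that fell held 53.9% ± 5.5 in white and 24.4% ± 1.5 in blue.

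By abundance, 246 clusters rose and 571 fell in blue above 100 CPM, and 1315 rose and 2614 fell from 10 to 100 CPM. From 1 to 10 CPM 2390 rose and 2007 fell, and under 1 CPM 1473 rose and 445 fell. As in red, library totals as the only scaling turned the direction above 100 CPM (465 rose and 389 fell) and from 10 to 100 CPM (2416 rose and 1425 fell).

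**Figure D2:**
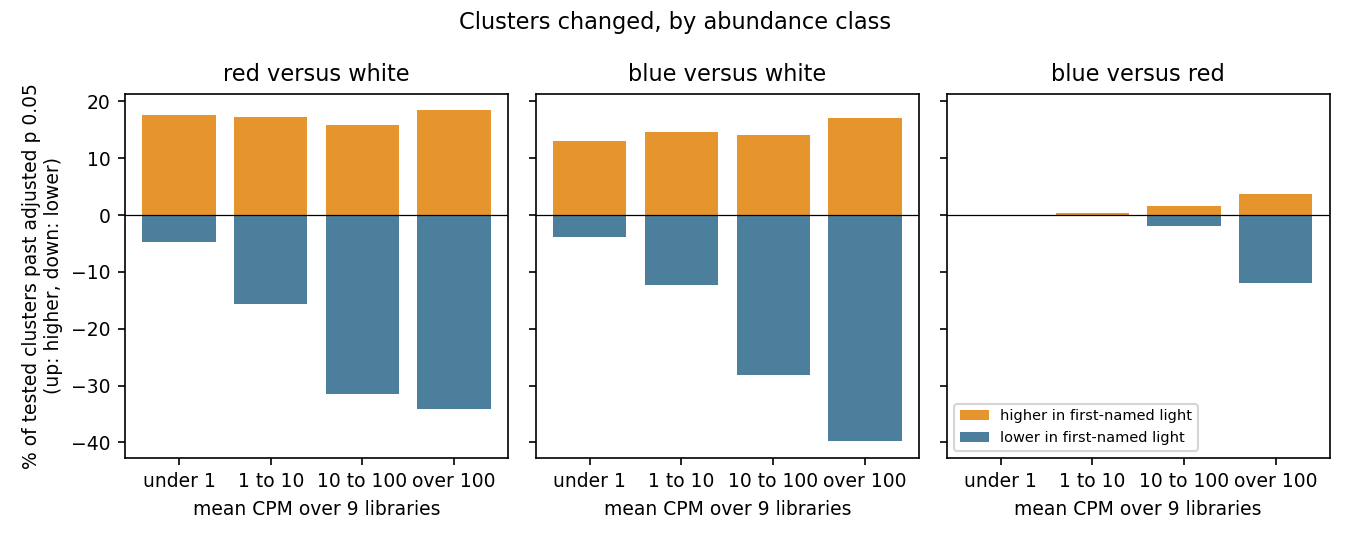
Percentage of the tested clusters (vertical axis) past an adjusted p of 0.05 in each comparison, in 4 classes of mean CPM over the 9 libraries (horizontal axis); bars above 0 are clusters higher in the light named first, bars below 0 clusters lower in it. Against white the lower bars lengthen with abundance, to 490 of 1435 clusters above 100 CPM in red and 571 of 1435 in blue, while few clusters under 10 CPM differ between blue and red; with library totals as the only scaling, higher calls outnumber lower ones against white above 10 CPM.

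In blue the clusters already named for red had the largest increase and decrease, so the rule took the next ones. The next in increase was Cluster-15686.48390 (5155 bases), with no counts in white and nearly equal levels under both narrow bands. Its mean was 277 ± 9.5 CPM in blue and 267 ± 13 CPM in red (SD, n = 3). It was at least 4250-fold higher in blue than in white (edgeR adjusted p = 1.7e-06) and at least 4110-fold higher in red (edgeR adjusted p = 2.1e-06). Its blue to red ratio was 1.03 (edgeR adjusted p = 0.94). The next in decrease was Cluster-15686.93187 (1806 bases), at 226 ± 35 CPM in white, with no counts in the 6 red and blue libraries. It was at least 4730-fold lower in blue (edgeR adjusted p = 0.00015) and at least 4960-fold lower in red (edgeR adjusted p = 0.00016).

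**Figure D3:**
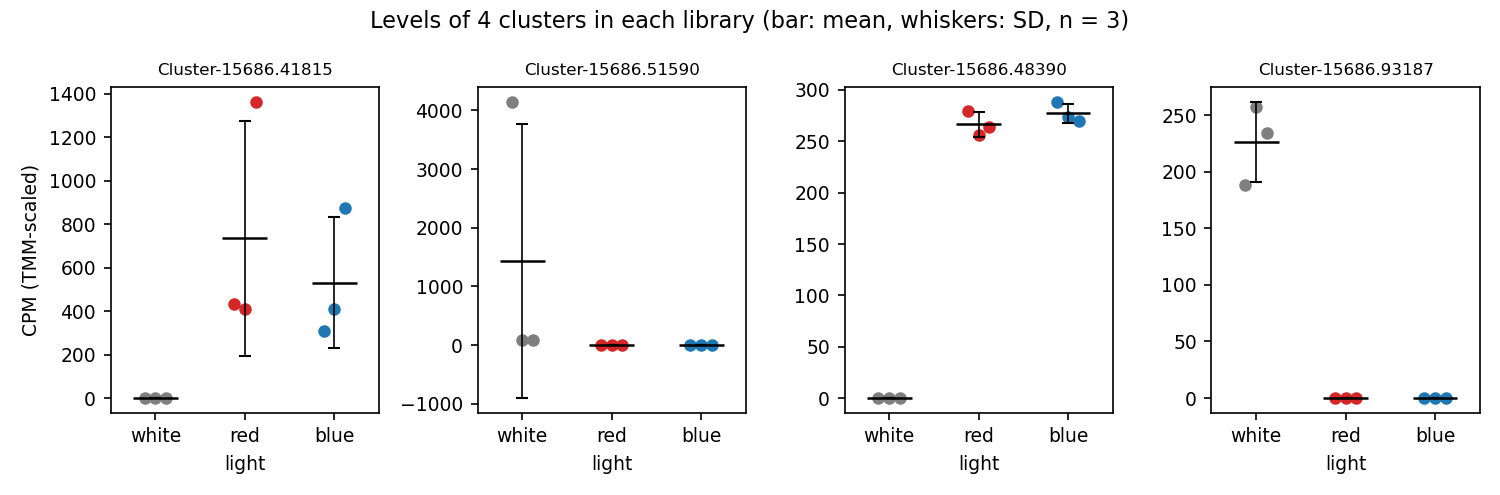
Level of the 4 named clusters in each library, in CPM on linear axes of different height (vertical axis), by light (horizontal axis); points are libraries, bars group means and whiskers SD (n = 3). Cluster-15686.48390 and Cluster-15686.93187 show little spread within a light, whereas the white mean of Cluster-15686.51590 rests on white 1 at 4140 CPM.

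In the comparison of blue with white, too, the count of changed clusters moved with the libraries used. It was 18125 without white 1, 7165 without blue 1 and 7050 without blue 2. With library totals as the only scaling, 8011 clusters rose and 3470 fell. The pooled spread bears on this count as on that of red, and a fit of the blue and white libraries alone called 7697 clusters.

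The responses to red and blue light were then set side by side. Most changes were shared: 4513 clusters rose and 4548 fell in both, against 923 and 952 for independent lists of these sizes. Another 29 clusters moved in opposite directions, 19 of them up in red and down in blue and 10 down in red and up in blue, where independent lists would give 1875. The number of such clusters was 12 to 55 with 1 library left out, 61 with library totals, 68 with DESeq2 and 4 with a 2-fold minimum. Across the 38376 clusters, which are not independent replicates, the log2 fold changes had a Pearson r of 0.919 and a Spearman rho of 0.899, and 88.0% had the same sign.

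Because both comparisons use the same 3 white libraries, some similarity is expected by chance. In 10 simulations of unchanged groups with the spread of each light, the mean Pearson r was 0.718 (range 0.704 to 0.729), the mean Spearman rho 0.717 and the share with the same sign 80.6%. The covariance of the log2 fold changes was 7.96, against 1.16 simulated, a difference of 6.80. The simulations gave on average 37.6 clusters called higher and 1.8 called lower in both, and none called in opposite directions. Unchanged groups give few calls whatever their spread, on average 43.9 in red and 46.6 in blue, and most of these were shared. The simulated numbers of calls thus do not show whether the observed calls were shared more than the common white libraries alone would bring. The simulations hold the chance spread of the shared white libraries. They do not hold a difference of the white group as a whole, such as a batch, which would enter both comparisons alike. The white libraries were too few to be split between the comparisons, so part of the excess may come from such a difference.

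**Figure D4:**
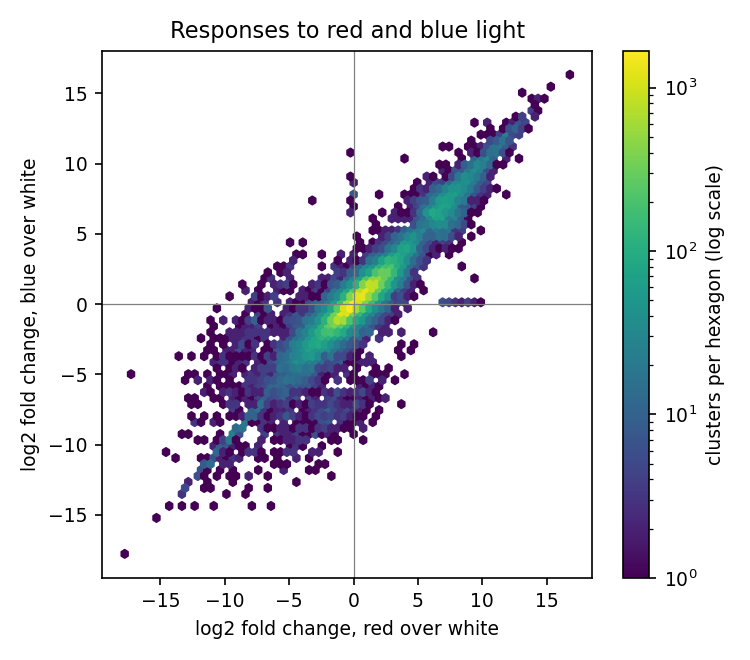
Log2 fold change of each tested cluster in blue over white (vertical axis) against red over white (horizontal axis); colour gives the number of clusters per hexagon on a log scale. Most clusters lie along the diagonal (Pearson r = 0.919 across clusters, beside 0.718 for simulated unchanged groups that share the white libraries).

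Blue light was compared with red light as the direct test of a difference between the narrow bands. In blue, 256 clusters were higher and 391 lower than in red, or 1.69% of those tested (edgeR's quasi-likelihood test, adjusted p under 0.05), and 147 and 210 of them differed at least 2-fold. The differences were found mostly among abundant clusters. Above 100 CPM, 52 clusters were higher and 171 lower in blue, 15.5% of that class, and from 10 to 100 CPM 145 were higher and 179 lower, or 3.49%; with library totals as the only scaling, 334 were higher and 169 lower in that second class, and 111 and 177 above 100 CPM. Under 1 CPM 18 clusters differed, with a median absolute log2 difference of 7.04, against 0.98 for those called above 100 CPM. Smaller differences among rare clusters may thus have been missed, and the shares do not compare the classes at equal reach. The 391 clusters lower in blue held 15% ± 0.24 of the counts in white, 17.0% ± 0.32 in red and 8.46% ± 0.14 in blue (SD, n = 3). The 256 clusters higher in blue held 2.63% ± 0.12 in white, 1.94% ± 0.018 in red and 4.03% ± 0.11 in blue.

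Set against white, the clusters lower in blue than in red were in large part those that fell in blue. Of the 391, 139 fell in blue and did not pass the threshold in red, 101 fell in both, 97 rose in red and did not pass in blue, 31 rose in both and 19 rose in red and fell in blue. Their median log2 change from white was -0.83 in blue and 0.07 in red. Of the 256 clusters higher in blue, 83 fell in red and did not pass in blue, 66 rose in blue and did not pass in red, 58 fell in both, 34 rose in both and 10 fell in red and rose in blue. Their median log2 change from white was 0.32 in blue and -0.74 in red.

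The spread in this test was estimated over all 3 lights, white included. A fit of the red and blue libraries alone called 3894 clusters, 2048 higher and 1846 lower in blue, among them all 638 of the 647 called with all libraries that it tested. Without 1 library the count was 1376 (white 1), 1341 (white 2), 235 (white 3), 147 (red 1), 120 (red 2), 132 (red 3), 200 (blue 1), 129 (blue 2) or 198 (blue 3), and library totals as the only scaling gave 544 clusters higher and 390 lower in blue.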

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

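The counts of changed clusters against white stayed within 1.5 times of the reported 13012 (red) and 11061 (blue) with RLE factors, library totals, DESeq2, limma-voom, no filter, a fit of the groups compared and a 2-fold minimum. They fell with a mean of at least 10 CPM (5456 in red and 5217 in blue, of 10738 clusters tested), with an adjusted p under 0.01 (6235 and 5651) and, as fewer clusters were tested (8842), among clusters with whole counts (4630 and 3928). Leaving out 1 library gave 7675 to 19979 in red and 7050 to 18125 in blue, in each case highest without white 1. Limma-voom with quality weights per group gave 9408 and 8150, of which 38.5% and 37.4% were higher, against 14747 and 12268 without the weights, of which 55.8% and 53.4% were higher. Library totals alone raised the shares of edgeR from 50.2% and 49.0% to 64.0% and 69.8%, and that of blue against red from 39.6% to 58.2%. The 647 clusters that differed between blue and red became 3894 in a fit of those groups, 3020 with quality weights per group, 2400 with DESeq2, 1178 at a mean of at least 10 CPM, 1074 with limma-voom, 357 with a 2-fold minimum, 139 at an adjusted p under 0.01, and 120 to 1376 with 1 library left out. Without the filter, 9 (main 18), 47 (82) and 179 (324) clusters differed between blue and red in the classes under 1, 1 to 10 and 10 to 100 CPM. The correlation of the red and blue responses, 0.919, was 0.804 without the filter, 0.964 at a mean of at least 10 CPM, 0.896 with limma-voom with or without quality weights, 0.941 among clusters with whole counts, and 0.871 to 0.923 with 1 library left out. The 29 clusters with opposite changes became 61 with library totals, 68 with DESeq2, 14 without the filter, 49 at a mean of at least 10 CPM, 8 at an adjusted p under 0.01, 4 with a 2-fold minimum, and 12 to 55 with 1 library left out. Except where stated, the cause of these shifts was not tested. No named cluster reversed. Cluster-15686.48390 and Cluster-15686.93187 passed in all 21 alternatives that tested them, in both comparisons with white (highest adjusted p 0.001 and 0.0087). Cluster-15686.41815 passed in 19 of 21 (lost with limma-voom, with or without weights, adjusted p 0.11 to 0.57). Cluster-15686.51590 passed in 12 of 20 in red and 6 of 20 in blue (adjusted p 0.00045 to 0.46), and DESeq2 gave it no adjusted p. None of the 4 was in the fit of clusters with whole counts, as each had a count that was not whole in some library. That alternative, which bears on reads divided between clusters, was thus not available for them.

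The labels number the samples 1 to 3 under each light. Libraries with the same number deviated together only weakly, but their correlations were all positive (0.0053 to 0.066). Those of libraries with different numbers ran from -0.066 to 0.04. Not every library correlated best with its own number, so the numbers were not read as pairs in the main fit, but a weak pairing stays possible. With the replicate block, 10033 clusters changed in red, 8567 in blue and 194 between blue and red, in place of 13012, 11061 and 647.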

Other observations

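Some clusters were present under white light and nearly absent under red and blue light, or the reverse. Against a floor of 3 counts per group, 238 clusters were at least 100-fold higher in white than in both red and blue, and 474 were at least 100-fold higher in both red and blue than in white; this limit was chosen after seeing the data. For this limit and the sums that follow, CPM use library totals without TMM. The 474 clusters summed to 19300 ± 400 CPM in red, 21700 ± 510 in blue and 20.5 ± 11 in white (SD, n = 3), and 469 of them passed the edgeR threshold against white in both comparisons. The 238 clusters summed to 28000 ± 5900 CPM in white, 39.8 ± 14 in red and 152 ± 140 in blue, and 192 passed in both comparisons. With a floor of 10 counts the numbers were 124 and 202, and with 1 library left out they ranged from 194 to 281 and from 361 to 483.

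The tests on mixed RNA, on depth, on a single outside source (in white 2, in white, in red and blue) and the fit with quality weights per light group were chosen after the result was seen. Of these, 3 replaced an earlier test whose result was known. For a single source in red and blue, the first test used the fit of all 9 libraries and was undecided. For the spread of the white libraries, the first test was a simulation whose expected outcome had been written down beforehand, and it met the outcome set against that explanation, but its outcome was fixed by its design. For depth, the first test thinned the libraries, but white 1 had the smaller total and more clusters detected than white 2, so thinning did not bear on it (the gap was 103% of that before). The results of the other first tests are given beside those that followed. For mixed RNA, a first limit of 5% took no account of the log scale and was dropped. The removal of the 100 most abundant clusters met the limits written beforehand, but those limits were wrong, since the removal left the values nearly where they were.

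The on-off clusters raise the question whether they belong to 1 organism with switched expression. A single outside source present only under red and blue would keep 1 blue to red ratio in all its clusters. In a fit of the red and blue libraries alone 30 of the 474 clusters were higher and 28 lower in blue, where that fit called 3894 of all 35237 clusters it tested. In the first test, with all 9 libraries, 4 were higher and 2 lower, short of the 10 in each direction that had been asked for. A single source present only in white would keep 1 ratio between white libraries, but the log2 ratio of white 2 to white 1 over the 238 clusters had an interquartile range of 5.36, with 104 clusters within 2-fold. These values argue against 1 such source behind all clusters of a set, but not behind part of them. Reads divided between near-identical clusters, such as alleles or isoforms, remain open: 86.4% of the 712 clusters had counts that were not whole in some library, beside 73.2% (67.0% to 77.2% in 200 draws) of clusters matched on mean CPM, an excess just under the 1.2-fold set for the test. Several outside sources, a source that itself responded to light, a genetic difference between the samples and regulation by light also stay open, untested.

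The white libraries differed more among themselves than the others. The totals argue against depth, as those of white 1 and white 2 differed 1.09-fold, while red 1 and red 2 differed 1.39-fold and still correlated at 0.912 against 0.802. An outside source in white 2 stays open. The 225 clusters at least 20-fold higher there than in white 1, red and blue had white 3 to white 2 ratios with an interquartile range of 2.94 on the log2 scale. A source shared by white 2 and white 3 would keep 1 ratio, but a source in white 2 alone sets none. Expression in white 3 itself could also widen the range. RNA of the red or blue samples in white 1 was judged on 463 clusters at least 100-fold higher in red and blue than in white 2 and 3. In white 1 they reached 4.39% of their red and blue level, which moves a 100-fold cluster 36.4% of the way on the log2 scale. White 1 lay 33.3% of the way along the first principal component. The ratio varied over the 68 clusters with enough counts (interquartile range 4.26), but expression in white 1 itself could add to it. Mixing would add its share of every red and blue cluster, however. The 474 clusters near 0 in white summed to 20.5 ± 11 CPM there (SD, n = 3), and to 19300 ± 400 in red. Selection for low white values does not lift that limit. These values argue against mixing of the size that the place of white 1 needs, but not against a trace. A few abundant clusters stay open too, as leaving out 100 of 38376 could hardly move the correlation of white 1 and white 2 (0.796, and 0.802 with all). Across clusters, white 1 minus white 2 correlated with red and blue minus white 3 (Pearson r = 0.338, Spearman rho 0.432). Part of the difference between white 1 and white 2 thus ran along that between white and the other lights. On the second principal component, with 10.9% of the variance, white 1 lay at 198.1 and white 2 at -151.2. Red and blue lay between -25.4 and -2 there, so a large part of the difference ran another way. What set the white samples apart, growth state included, was not tested.

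In the main fit, among rare clusters changed in red most rose, and among abundant ones most fell. With library totals only, the abundant part of this turned, with 415 that rose and 324 that fell above 100 CPM. The share of higher calls was still 28.2 percentage points larger under 1 CPM than above 100 CPM (43.7 with TMM). That gap cannot set scaling aside, as the test took it that 1 factor per library moves all classes alike. The median absolute log2 change of called clusters was 4.38 under 1 CPM and 0.919 above 100 CPM, so 1 shift turns abundant calls more easily. Counts taken up by a few abundant clusters stay open, as the share was 45.2 points larger under 1 CPM than from 10 to 100 CPM both with and without the 100 most abundant, and the larger spread of the white libraries stays open as well. In limma-voom with quality weights per light group the difference between those classes was -26.7 points (83 clusters under 1 CPM higher and 534 lower), against 32.8 without weights (2023 and 647). The median log2 fold change of all clusters hardly moved (0.433 with weights and 0.434 without), so the sign of the gap turned because calls of higher clusters were lost. The weights did not bring the gap to within 10 points of 0. The value was thus read as undecided, after it had for a time been read as favouring the explanation. The simulation decides nothing, as unchanged groups give few calls whatever their spread (0 under 1 CPM higher in red in 10 simulations).

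The 6 libraries of a comparison allow 10 splits into 3 and 3, too few for a share under 0.05. In each comparison 1 split, the real one, gave a count as large as the real one. Red against white gave 13012 clusters and at most 1 in another split, blue against white 11061 and at most 0, and blue against red 647 and at most 1. The other splits mix both lights in each group, so the light difference adds to the spread and few calls follow by design. These counts thus decide nothing.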
